A study of Homo sapiens with 12 samples.

How the data were processed

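MCF7, an established oestrogen receptor-positive human breast cancer line, was profiled in 12 libraries of mRNA sequencing. Per the labels the cells were "EV control" or "FAH WT" and had received vehicle (DMSO in the titles) or 200 nM abemaciclib, a CDK4/6 inhibitor, for 3 days, giving 4 groups of 3 libraries. The groups are called EV cells and FAH cells here, and the labels used do not spell out EV or give the length of the vehicle treatment. Culture medium, column extraction of RNA, poly-T bead selection and a NEBNext Ultra library at Novogene are stated in the labels for all samples alike. The labels do not say that the 3 numbered replicates were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

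The deposited tables hold transcripts. Per the file headers they give length, effective length, length-scaled abundance (TPM) and the estimated count of reads for each transcript. The submitters' processing notes name Salmon 1.4.0 and hg38 without stating what each was used for or the order of steps. The transcript index and the annotation release were not given in the sources used here. The deposited counts are expected counts, so reads shared by near-identical transcripts were divided by estimation, and genes with close copies are less certain. Per library the deposited counts summed to between 26644421 and 38102049 reads.

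Transcripts were matched to GENCODE 29 (hg38) by identifier without its version. Of 242934 transcripts 195743 matched, 88.2% of these with the same version, and 47191 did not match. The unmatched transcripts carried between 6.84% and 7.21% of the reads of a library and were left out of gene totals. The counts of matched transcripts were summed to 55383 genes and rounded to whole numbers. Current symbols were used for 55006 of these genes. Sequence-level questions, such as a change in the coding sequence of FAH, were not analysed here.

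Genes were filtered with filterByExpr, scaled with TMM and fitted in edgeR 4.0.16 by quasi-likelihood (glmQLFit with robust=TRUE, glmQLFTest) with 1 coefficient per group and no replicate term, on 16832 genes. The prior degrees of freedom were 7. The contrasts were abemaciclib minus vehicle in EV cells, the same in FAH cells, FAH minus EV cells under vehicle, FAH minus EV cells under abemaciclib, and the difference between the 2 abemaciclib responses. A gene was called when its Benjamini-Hochberg adjusted p was below 0.05. Fold changes are log2 with the standard error of edgeR's estimate, gene levels are depth-scaled counts (CPM) with SD, and n is 3 libraries per group throughout.

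The 26 gene lists were written from general knowledge, with between 8 and 45 tested members each, and were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists within each comparison. Members below the filter or without a matched transcript were not tested. Beside the counts of called members, counts after adjustment over the list alone are given. Camera with an estimated correlation and fry were alternatives. For list scores, log2(CPM + 1) was averaged over the members and compared by exact two-sided permutation, whose smallest possible p with 3 against 3 libraries is 0.1.

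The named genes follow a rule that was fixed before the data were examined, as were the contrasts, the lists, the filter, the scaling and the first set of alternative settings. The rule takes a panel of 18 genes (FAH, CCND1, CDK4, CDK6, CCNE1, CCNE2, CDK2, RB1, E2F1, MKI67, MCM2, CCNA2, CCNB1, CDKN1A, ESR1, MYC, MALAT1 and NEAT1). It adds the 8 called genes that rose most and the 8 that fell most in each comparison, given a proper symbol, a mean of at least 2 log2 CPM in the higher group and, except for the response difference, no overlap between the libraries compared. It further adds the 4 members with the smallest p of each list and each member whose direction counts at most 3. Genes named outside the rule are marked as chosen after the values were seen.

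The alternative settings chosen at that time were RLE scale factors, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter (100 reads in total and 1 CPM in 3 libraries), transcript length offsets, fits of only the groups compared, an additive replicate block, each library left out in turn and a test against a fold of 1.5 (glmTreat). For lists the estimated correlation, fry and a test without FAH were added, and for FAH the TPM and its most abundant transcript alone. Settings chosen after the data were seen were transcripts with retained introns left out, unmatched transcripts kept as features, the GC trend of each library removed (alone and for the correlations), a replicate block within EV cells, that block with the GC trend removed, and an estimated correlation for the tyrosine list without FAH.

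The closeness of libraries was measured on log2 CPM with a prior count of 2 and genes at or above a mean of 4. Residual correlations were used to check whether equal replicate numbers were paired. They were 0.38, 0.33 and 0.21 between EV vehicle and EV abemaciclib libraries of the same number, and -0.22, 0.07 and -0.2 for FAH cells. This is a hint from the data about EV cells only, since the labels give numbers without a meaning, so both kinds of block were run as alternatives.

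The tests were tried on simulated data built from the mean of each gene, the library sizes and the tagwise dispersions, with 67 genes changed at 1.5-fold, 67 at 2-fold and 66 at 4-fold. This self-test was first run after the main analysis. At 1.5-fold edgeR recovered 64.2% (EV cells), 62.7% (FAH cells), 67.2% (genotype under vehicle), 64.2% (genotype under abemaciclib) and 49.3% (response difference) of the changed genes. At 2-fold the recovery was 83.6%, 88.1%, 92.5%, 80.6% and 80.6%, and at 4-fold 98.5%, 100.0%, 98.5%, 98.5% and 93.9%. Unchanged genes made up 5.7%, 6.2%, 3.4%, 4.7% and 6.3% of the calls. A simulated list of 40 genes shifted by 1.2-fold was called in each comparison, and 0 of 20 unshifted lists were. Correlation between genes was not among the inputs of the simulation. In the real lists its estimate for abemaciclib in EV cells ran from -0.037 (basal markers) to 0.853 (mitochondrially encoded mRNAs). The simulated lists therefore cannot show how often camera falsely calls lists whose genes move together. Software was R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.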

Results

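Abemaciclib left MCF7 cells of both genotypes with far lower mRNA of mitosis and DNA replication genes, and with more modestly lower mRNA of cholesterol and fatty acid genes. Oestrogen receptor targets were lower by less, calls lost with an estimated correlation between genes (camera adjusted p = 0.216 in EV and 0.162 in FAH cells). FAH cells carried 7.95 times the FAH mRNA of EV cells under vehicle, and edgeR called few other genes there. Under abemaciclib, cell cycle genes were higher and interferon-stimulated genes lower in FAH than in EV cells, the latter call being lost with an estimated correlation (camera adjusted p = 0.0761). MCF7 is an oestrogen receptor-positive breast cancer line, abemaciclib inhibits CDK4 and CDK6, and FAH encodes fumarylacetoacetase, the enzyme of the last step of tyrosine degradation. The 4 groups of 3 libraries were EV or FAH cells given vehicle or 200 nM abemaciclib for 3 days. The series title speaks of a non-canonical function of FAH and of resistance to CDK4/6 inhibitors, and the genotype comparison under abemaciclib bears on it. Each library held between 26644421 and 38102049 reads, and edgeR tested 16832 genes. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

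FAH mRNA rose in FAH cells to 112.0 ± 2.72 CPM from 14.1 ± 1.21 CPM in EV cells under vehicle (mean ± SD, n = 3 per group, log2 fold change 2.99 ± 0.07 SE, edgeR adjusted p = 4.7e-13). Under abemaciclib it stood at 118.3 ± 4.75 against 13.9 ± 0.638 CPM (3.09 ± 0.07, 8.51-fold, edgeR adjusted p = 3.24e-13). Abemaciclib did not change it measurably in EV cells (-0.02, edgeR adjusted p = 0.868) or in FAH cells (0.08, edgeR adjusted p = 0.365). With the deposited TPM the FAH ratios were 8.24-fold and 9.37-fold, and for its most abundant transcript alone 12.35-fold and 20.49-fold. The last is uncertain, since reads are divided by estimation between that transcript (FAH-213) and FAH-201, and EV abemaciclib library 1 had 0 reads on the former and 221.7 on the latter, where libraries 2 and 3 had 246.2 and 157.9 on the former. The gene lies on chromosome 15, from 80152490 to 80186946 on the plus strand of hg38 (ENSG00000103876.12).

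**Figure D1:**
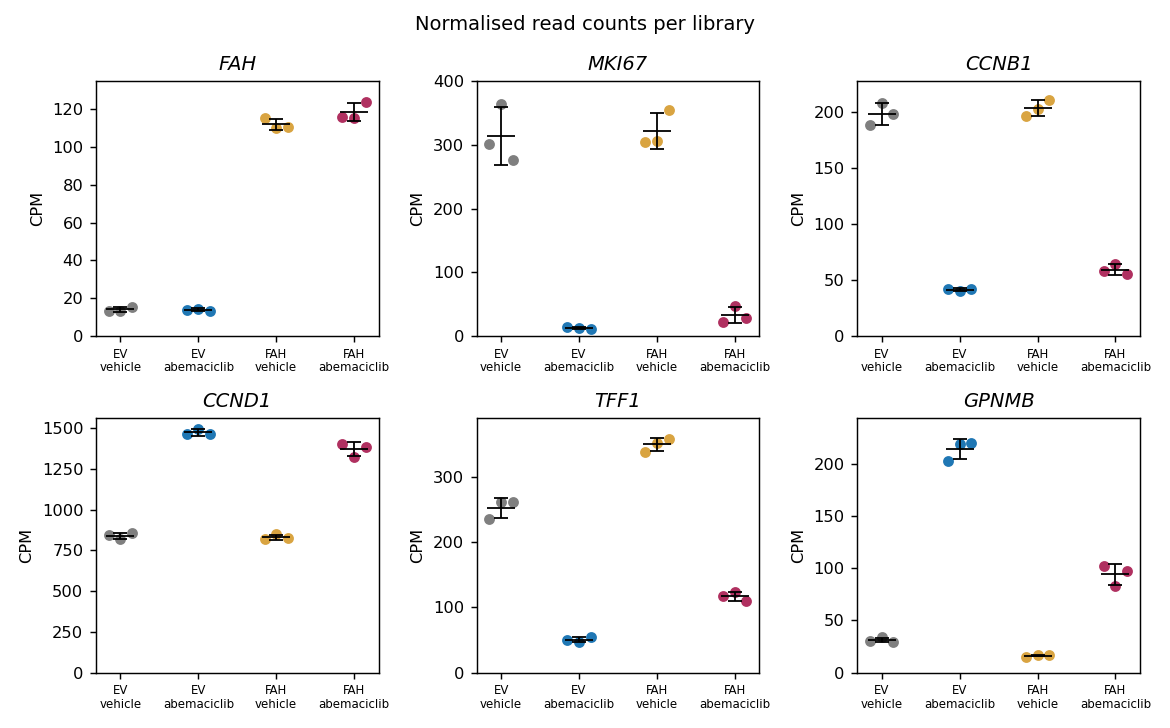
Read counts scaled to depth (CPM) of FAH, MKI67, CCNB1, CCND1, TFF1 and GPNMB in the 4 groups, with 1 point per library and bars at mean and SD (n = 3). FAH stood at 14.1 and 112.0 CPM in EV and FAH cells under vehicle, and MKI67 at 12.1 and 32.7 CPM in EV and FAH cells under abemaciclib.

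In EV cells abemaciclib lowered the proliferation marker MKI67 from 314.2 ± 45.7 to 12.1 ± 1.74 CPM (log2 fold change -4.69 ± 0.28, n = 3 per group, edgeR adjusted p = 1.58e-06). The mitotic kinase AURKB fell from 67.2 ± 2.52 to 2.47 ± 0.464 CPM (-4.76 ± 0.20, edgeR adjusted p = 3.28e-09). PIMREG, a mitotic regulator, fell as well (-5.40 ± 0.20, edgeR adjusted p = 5.28e-11). CCND1, which encodes the cyclin partner of CDK4 and CDK6, rose from 839.4 ± 17.0 to 1474 ± 19.3 CPM (0.81 ± 0.04, edgeR adjusted p = 3.85e-10). The glycoprotein gene GPNMB rose from 31.2 ± 2.21 to 214.2 ± 9.44 CPM (2.78 ± 0.08, edgeR adjusted p = 2.34e-12). In all 5903 of 16832 genes were called, 2911 higher and 2992 lower, of which 383 and 623 moved at least 2-fold.

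The proliferation lists gave the lowest values. All 45 mitosis and G2/M genes fell (median -3.60, camera adjusted p = 6.94e-177), among them PBK (-4.17 ± 0.10), AURKA (-2.82 ± 0.08), UBE2C (-3.66 ± 0.11) and CCNB1 (-2.26 ± 0.06), which encodes the cyclin of mitotic entry. Of 44 DNA replication genes 43 fell and 1 did not pass (43 with adjustment over the list alone, median -1.72, camera adjusted p = 1.26e-108), with the helicase genes MCM2 (-1.37 ± 0.06), MCM6 (-1.71 ± 0.05) and CDC45 among them. Homologous recombination and Fanconi genes fell in 19 of 21 cases (21 over the list alone, median -2.11, camera adjusted p = 5.93e-40), including BRCA1 (-2.71 ± 0.12) and RAD51 (-2.94), both needed for strand repair. Of 26 genes of the CDK4/6-RB axis 8 rose and 10 fell (8 and 11 over the list alone), and the list was not called (median -0.15, camera adjusted p = 0.0917). CDK6 rose (0.75 ± 0.07) and CCNE2 (-3.75 ± 0.21), E2F1 (-2.19 ± 0.14), CDK2 (-1.13 ± 0.06), CCNE1 (-0.49 ± 0.14) and RB1 (-0.45 ± 0.07) fell, while CDK4 did not pass (-0.03 ± 0.06, edgeR adjusted p = 0.807). Without EV vehicle library 2 CDK4 was called at -0.12 (edgeR adjusted p = 0.0135).

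Lipid synthesis genes fell as a group. Of 24 cholesterol genes 20 fell and 1 rose, TM7SF2 at 0.40 (same counts over the list alone, median -0.70, camera adjusted p = 2.85e-24), and the fallers included ACAT2 (-2.02 ± 0.08), INSIG1 (-1.16) and HMGCS1 (-0.99), the last encoding an early enzyme of the pathway. Of 14 fatty acid synthesis genes 12 fell and PLIN2 rose at 0.57 (same over the list alone, median -0.34, camera adjusted p = 8.58e-10). The desaturase gene SCD went from 1482 ± 49.4 to 563 ± 8.47 CPM (-1.40 ± 0.04, edgeR adjusted p = 3.06e-12). TCA cycle genes fell in 15 of 25 cases and IDH3G alone rose at 0.19 (16 and 1 over the list alone, median -0.27, camera adjusted p = 0.0015), for instance FH (-0.84) and IDH2 (-0.55). Nuclear respiratory chain genes (3 rose, COX4I1 0.15, COX7C 0.26 and UQCRB 0.27, 12 fell, median -0.12, camera adjusted p = 0.153) and glycolysis and hypoxia genes (4 rose, 11 fell, median -0.10, camera adjusted p = 0.346) were not called as lists. Among the latter the aldolase gene ALDOC (-1.62) fell and PFKM (0.91) and VEGFA (0.78) rose, VEGFA, chosen after the values were seen, encoding a growth factor for vessels.

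Oestrogen receptor targets were mostly lower in EV cells given abemaciclib, with 13 of 24 falling and 5 rising (14 and 5 over the list alone, median -0.25, camera adjusted p = 0.00707, adjusted p = 0.216 with an estimated correlation). The classical target TFF1 fell from 252.4 ± 15.1 to 50.4 ± 3.62 CPM (-2.32 ± 0.07, edgeR adjusted p = 2.34e-12), AREG fell by 1.54, and ESR1, the receptor gene itself, fell by 0.32 ± 0.05. The risers were NRIP1 (0.18), PGR (0.27), STC2 (0.45), HSPB8 (0.72) and RET (0.87), named after the values were seen. Luminal identity genes went both ways (6 rose, ESR1 and AGR2 fell, median 0.14, camera adjusted p = 0.484), with the secreted AGR2 at -1.44 ± 0.05 and the transcription factor genes ELF3 (0.81) and GATA3 (0.25) higher. Of the basal and mesenchymal markers CDH3 (0.64) and TP63 (1.24) rose and FOXC1 (-0.40) fell, with the list not called (median 0.09, camera adjusted p = 0.346). Of the stromal markers edgeR called FBLN1, a matrix gene, in the fit of all groups (-0.71, edgeR adjusted p = 0.0288, 0 over the list alone, list median -0.07, camera adjusted p = 0.886), and lost it with length offsets (0.341) or no low-count filter (0.0946). COL1A1 was called with the GC trend removed (-0.35, edgeR adjusted p = 0.00657), with a block within EV cells as well (0.00275), or without EV vehicle 2 (0.0212). The FBLN1 call was lost in 4 of 6 fits with 1 library left out, namely without EV vehicle 2 (0.0924), EV vehicle 3 (0.0789), EV abemaciclib 1 (0.109) or EV abemaciclib 2 (0.0603).

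Lysosome genes and the tested part of the NF-kB and secretory list leaned higher. Of 32 lysosome and autophagy genes 23 rose and GLA fell at -0.27 (25 and 1 over the list alone, median 0.49, camera adjusted p = 6.33e-09, adjusted p = 0.0524 with an estimated correlation), among them the protease gene CTSA (0.78 ± 0.05) and PSAP (0.70). Of 13 NF-kB and secretory senescence genes 7 rose and 0 fell (median 0.65, camera adjusted p = 0.00707, adjusted p = 0.0578 with an estimated correlation), with ICAM1 (1.01), RELB (0.96) and LIF (1.03). Their median was 0.42 without EV abemaciclib 1. Of 27 listed members only these 13 were tested, and the cytokine genes IL6, CXCL8, IL1A, IL1B, CCL2 and CSF2 were below the filter. IGFBP5, an insulin-like growth factor binding protein, reached 718.0 ± 25.4 from 343.1 ± 13.5 CPM (1.07 ± 0.05, edgeR adjusted p = 1.31e-10). Of 23 p53 targets 8 rose and 6 fell (median 0.07, camera adjusted p = 0.153), with the CDK inhibitor gene CDKN1A (0.41 ± 0.06), TP53INP1 (1.02 ± 0.07) and BTG2 (1.14) higher and PLK2 (-0.50) lower. Interferon-stimulated genes rose in 7 of 29 cases and fell in 0 (3 and 0 over the list alone, median 0.41, camera adjusted p = 0.0868), for instance SAMD9 (1.10) and PARP14 (0.61). Antigen presentation genes rose in 5 of 14 cases, such as ERAP1 (0.32) and NLRC5 (1.12), and CALR (-0.59) and PDIA3 (-0.48) fell (median 0.35, camera adjusted p = 0.558). HLA-A, HLA-C, HLA-E, HLA-DRA, PSMB8 and PSMB9 were below the filter, so this list lacks them in every comparison. The filter saw only reads of matched transcripts, so this does not show that these genes were not expressed. With transcript length offsets ERAP1 (edgeR adjusted p = 0.388) and NLRC5 (edgeR adjusted p = 0.241) were no longer called.

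Stress and biosynthesis lists leaned lower. ATF4 and amino acid response genes fell in 13 of 29 cases and 4 rose, SARS1 (0.23), STC2 (0.45), DDIT3 (0.99) and DDIT4 (1.49), chosen after the values were seen (median -0.19, camera adjusted p = 0.00707, adjusted p = 0.157 with an estimated correlation), the fallers including the serine synthesis gene PHGDH (-2.19) and the transporter gene SLC7A5 (-1.49 ± 0.07). Of 16 ER chaperone genes 8 fell, such as HSP90B1 (-0.83), and EDEM1 (0.18) and DNAJB9 (0.26) rose (3 and 8 over the list alone, median -0.37, camera adjusted p = 0.00682, adjusted p = 0.131 with an estimated correlation). Ribosome biogenesis and MYC targets were not called as a list (2 rose, 9 fell, median -0.09, camera adjusted p = 0.13), with ODC1, the polyamine synthesis gene, at -0.85. Of 15 tyrosine and phenylalanine genes COMT rose (0.33) and 5 fell, GOT1 (-1.01 ± 0.07), GOT2 (-0.39), GCH1 (-0.55), PCBD2 (-0.35, chosen after the values were seen) and MIF (-0.24) (median 0.00, mean -0.03, camera downward, adjusted p = 0.337). Of the mitochondrially encoded mRNAs MT-ND6 (0.59), MT-ND3 (0.57) and MT-ND1 (0.43) rose (2 over the list alone, median 0.28, camera adjusted p = 0.0654), and MT-ND1 was lost without EV abemaciclib 2 (edgeR adjusted p = 0.122) or 3 (0.127). The share of mitochondrial reads in the EV libraries was 4.14, 4.35 and 2.84% under vehicle and 4.48, 5.01 and 5.19% under abemaciclib.

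Among the remaining named genes of EV cells, ATG9B (2.36 ± 0.25), SERPINA11 (2.36), NUDT19-DT (2.52) and RENBP (2.33 ± 0.16) rose, and PIF1 (-4.82), MND1 (-4.68), ITGA2B (-4.62), NUSAP1 (-4.60) and CDCA3 (-4.56) fell. PSG5 (3.22 ± 0.20) and PSG4 (2.78 ± 0.19), pregnancy-specific glycoprotein genes, rose with an uncertain split between them, since they are near copies. The nuclear RNAs NEAT1 (1.42 ± 0.19, edgeR adjusted p = 0.000404) and MALAT1 (0.93 ± 0.20, edgeR adjusted p = 0.00571) rose, while the share of reads on transcripts with retained introns went from 3.90, 4.12 and 4.03% to 5.04, 4.21 and 4.44%. MYC rose by 0.20 ± 0.07 (edgeR adjusted p = 0.0426), a call lost without EV vehicle 1 (0.125), EV vehicle 2 (0.165), EV abemaciclib 2 (0.261) or EV abemaciclib 3 (0.13) and with RLE factors, limma-voom, length offsets, a replicate block or the GC trend removed (0.0528 to 0.242). SIPA1L2 (4.12 ± 1.29, edgeR adjusted p = 0.037) was lost without EV vehicle 1 (0.109), EV vehicle 3 (0.11) or any EV abemaciclib library (0.079, 0.0773 and 0.0702), and with the replicate block within EV cells (0.0593). OAS2, an interferon-stimulated gene (1.24, edgeR adjusted p = 0.0291), was lost without EV vehicle 1 (0.0937), EV vehicle 3 (0.0928), EV abemaciclib 1 (0.0525) or EV abemaciclib 3 (0.106), and with that block (0.0678).

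**Figure D2:**
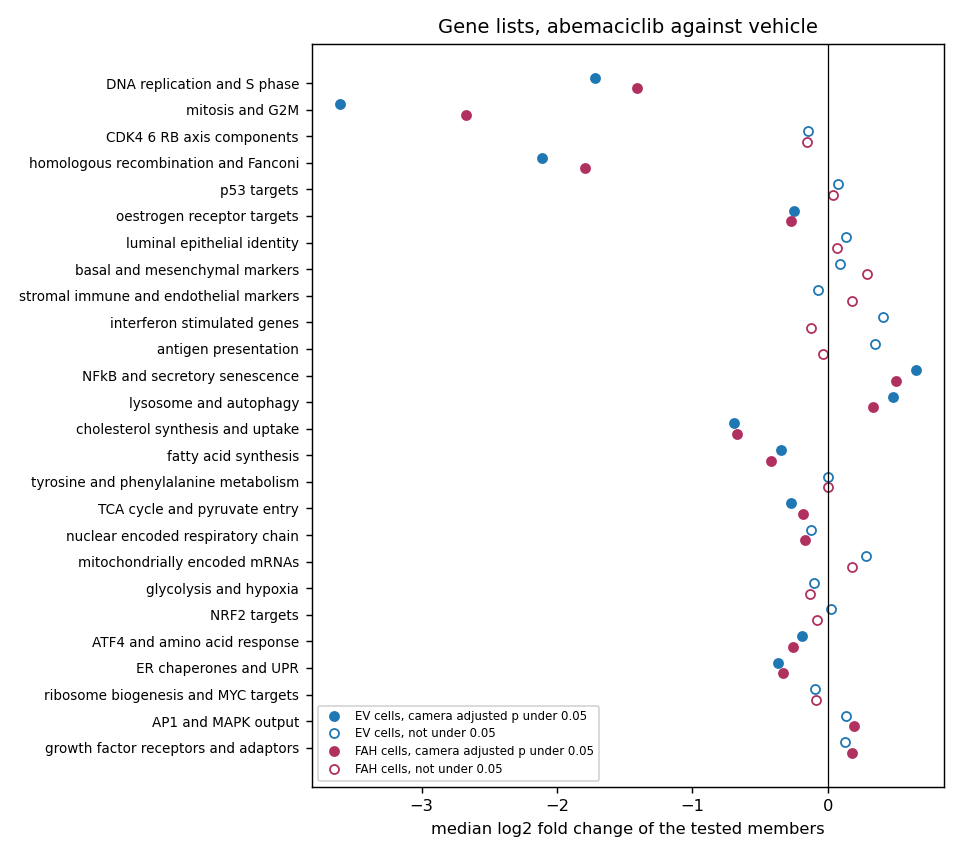
Median log2 fold change by abemaciclib over the tested members of each list (horizontal axis) in EV and FAH cells, n = 3 libraries per group, without error bars. The mitosis list stood at -3.60 in EV cells and -2.67 in FAH cells.

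In FAH cells abemaciclib changed many of the same genes, with smaller falls of cell cycle genes. MKI67 fell from 322.2 ± 28.5 to 32.7 ± 12.6 CPM (log2 fold change -3.31 ± 0.25, n = 3 per group, edgeR adjusted p = 1.25e-05) and AURKB from 66.8 ± 1.86 to 6.18 ± 2.15 CPM (-3.45 ± 0.18, edgeR adjusted p = 3.59e-08). CCND1 rose from 831.6 ± 14.6 to 1372 ± 42.0 CPM (0.72 ± 0.04, edgeR adjusted p = 2.36e-09), and GPNMB from 16.4 ± 0.91 to 94.2 ± 10.1 CPM (2.53 ± 0.08, edgeR adjusted p = 3.37e-11). A total of 4964 genes were called, 2334 higher and 2630 lower, with 281 and 491 moving at least 2-fold.

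All 45 mitosis genes fell again (median -2.67, camera adjusted p = 1.9e-156), with PBK (-2.80 ± 0.09), UBE2C (-2.64), AURKA (-2.20) and CCNB1 (-1.79 ± 0.06) lower. DNA replication genes fell in 43 of 44 cases (44 over the list alone, median -1.41, camera adjusted p = 8.52e-98), with MCM2 (-1.14) and MCM6 (-1.27 ± 0.05) among them. Repair genes of homologous recombination fell in 20 of 21 cases (21 over the list alone, median -1.79, camera adjusted p = 2.33e-36), with BRCA1 (-2.05) and RAD51 (-2.49). In the CDK4/6-RB axis 8 genes rose and 11 fell (8 and 13 over the list alone, median -0.15, camera adjusted p = 0.104), CDK6 (0.79 ± 0.07) upward and CCNE2 (-2.45 ± 0.19), E2F1 (-1.76) and CDK2 (-1.02) downward. CCNE1 (-0.17, edgeR adjusted p = 0.395), CDK4 (-0.12, edgeR adjusted p = 0.186) and RB1 (-0.19, edgeR adjusted p = 0.0724) did not pass. With the GC trend removed CDK4 (0.0284) and RB1 (0.0311) were called, as they were from only the groups compared (0.0177 and 0.0176).

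Of the cholesterol genes 20 of 24 fell and 0 rose (21 and 1 over the list alone, median -0.67, camera adjusted p = 8.71e-27), with ACAT2 (-1.80) and INSIG1 (-1.07). Fatty acid genes fell in 11 cases and PLIN2 rose at 0.88 (same over the list alone, median -0.42, camera adjusted p = 1.98e-11). SCD went from 1557 ± 56.9 to 664 ± 1.72 CPM (-1.23 ± 0.04). TCA cycle genes fell in 13 cases, FH (-0.68) and IDH2 (-0.42) among them, and rose in 0 (15 and 1 over the list alone, median -0.19, camera adjusted p = 0.00447, adjusted p = 0.0602 with an estimated correlation). Oestrogen receptor targets fell in 11 cases and rose in 4, HSPB8 (0.76) and, chosen after the values were seen, NRIP1 (0.19), STC2 (0.36) and RET (0.36) (13 and 4 over the list alone, median -0.27, camera adjusted p = 0.00402, adjusted p = 0.162 with an estimated correlation). TFF1 fell from 349.2 ± 9.68 to 116.9 ± 6.61 CPM (-1.58 ± 0.06, edgeR adjusted p = 8.13e-11), AREG fell by 1.13 and ESR1 by 0.38. Without FAH vehicle 3 the median of these targets was -0.17. Lysosome genes rose in 18 cases, including GNS (0.57) and CTSA (0.45), while GLA (-0.42) and NPC1 (-0.25) fell (20 and 2 over the list alone, median 0.34, camera adjusted p = 2.13e-06, adjusted p = 0.103 with an estimated correlation).

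NF-kB and secretory genes rose in 6 cases and fell in 0 (8 and 0 over the list alone, median 0.50, camera adjusted p = 0.00323, adjusted p = 0.0602 with an estimated correlation), with IGFBP5 (1.14 ± 0.05) and RELB (0.79). ATF4 genes fell in 11 cases, for instance PHGDH (-2.06) and SLC7A5 (-1.31), and STC2 (0.36), DDIT3 (0.46) and DDIT4 (1.19) rose (3 and 13 over the list alone, median -0.26, camera adjusted p = 0.00186, adjusted p = 0.109 with an estimated correlation). ER chaperone genes fell in 8 cases, such as HSP90B1 (-0.63), and DNAJB9 rose (0.70) (2 and 9 over the list alone, median -0.33, camera adjusted p = 0.0216, adjusted p = 0.162 with an estimated correlation). The chaperone call was lost without FAH abemaciclib library 2 (median -0.26, camera adjusted p = 0.066). Nuclear respiratory chain genes fell in 12 cases, such as NDUFB10 (-0.41), and COX4I1 (0.14), UQCRB (0.20) and COX7C (0.21) rose (4 and 12 over the list alone, median -0.17, camera adjusted p = 0.049, adjusted p = 0.436 with an estimated correlation). That call was lost without FAH abemaciclib 2 (0.128), FAH abemaciclib 3 (0.103), FAH vehicle 2 (0.0653) or FAH vehicle 3 (0.0528), and with RLE factors (0.0537), length offsets (0.104) or a replicate block (0.0566).

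Mitochondrially encoded mRNAs were not called as a list in FAH cells (median 0.18, camera adjusted p = 0.19), and their single calls hung on the fit. With all groups fitted edgeR called 0 of them, while MT-ND6 was called higher with DESeq2 (0.00832), limma-voom (0.0341) and length offsets (0.0382), and MT-ND3 with DESeq2 (0.0407). From only the groups compared edgeR called MT-ND6 (0.000805), MT-ND5 (0.0042), MT-CO1 (0.0136) and MT-ND3 (0.0293). Of the interferon-stimulated genes edgeR called none higher there, and HERC5 (-0.89, edgeR adjusted p = 0.00669) and USP18 (-0.58, edgeR adjusted p = 0.0321) fell (0 and 1 over the list alone, median -0.13, mean 0.02, camera adjusted p = 0.498). USP18 was lost without FAH vehicle 2 (0.121), FAH vehicle 3 (0.112), FAH abemaciclib 2 (0.136) or FAH abemaciclib 3 (0.065). CMPK2 (-0.80, edgeR adjusted p = 0.05) was called lower under 6 other settings (0.0211 to 0.0488) and without FAH vehicle 1 (0.0401). HERC6 (-0.43, 0.0632) was called without a low-count filter (0.032) and without FAH vehicle 1 (0.0456) or FAH abemaciclib 1 (0.0211). CALR (-0.52) and PDIA3 (-0.37), which load antigen, also fell, AGR2 fell by 1.21, and TP63 (2.49, edgeR adjusted p = 3.66e-05) and CDH3 (0.57) rose. CDKN1A rose by 0.23 ± 0.06 (edgeR adjusted p = 0.0094), lost without FAH vehicle 1 (0.0531), and MYC by 0.24 (edgeR adjusted p = 0.0217), lost without FAH vehicle 1 (0.0846), FAH vehicle 2 (0.0959), FAH abemaciclib 1 (0.0916) or FAH abemaciclib 2 (0.0611). NEAT1 (0.95) and MALAT1 (1.02) rose, as did the integrin gene ITGB6 (2.07 ± 0.14), SLC14A1 (2.28), DPH1 (2.26) and the near copies PSG5 (2.40) and PSG4 (2.30). TMEM265 (3.13, edgeR adjusted p = 0.0309) was lost in 5 of 6 fits, at most at 0.0724 without FAH abemaciclib 3. SFT2D3 stood at 11.6 ± 3.84 CPM against 0 CPM (edgeR adjusted p = 0.0152), lost with limma-voom (0.0607) and a replicate block (0.0571). PIMREG (-3.46 ± 0.16), PIF1 (-3.46), PTTG1 (-3.38), ITGA2B (-3.31) and CDCA3 (-3.30) fell. Medians for the other lists not called were 0.04 for p53 targets, 0.07 for luminal identity (camera downward), 0.29 for basal markers, 0.18 for stromal markers (mean 0.03, camera downward), 0.00 for tyrosine genes (mean 0.08, camera downward), -0.04 for antigen presentation, -0.13 for glycolysis and -0.09 for ribosome biogenesis.

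With an estimated correlation 6 list calls held in EV cells (mitosis, replication, homologous recombination, cholesterol, fatty acid and TCA genes) and 5 in FAH cells (the same without TCA genes). Between the genotypes 1863 genes rose in both and 2183 fell in both, against 403.7 and 467.5 expected for unrelated calls, and 2 were called in opposite directions. Those 2, HNRNPR and a long non-coding RNA without a symbol, were chosen after the values were seen and had standard errors near or above 1.22, with HNRNPR at -6.01 ± 2.01 in EV cells and 6.26 ± 1.95 in FAH cells (edgeR adjusted p = 0.0391 and 0.0333). The responses correlated at Pearson 0.539 and Spearman 0.673 over genes, which are not independent replicates.

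**Figure D3:**
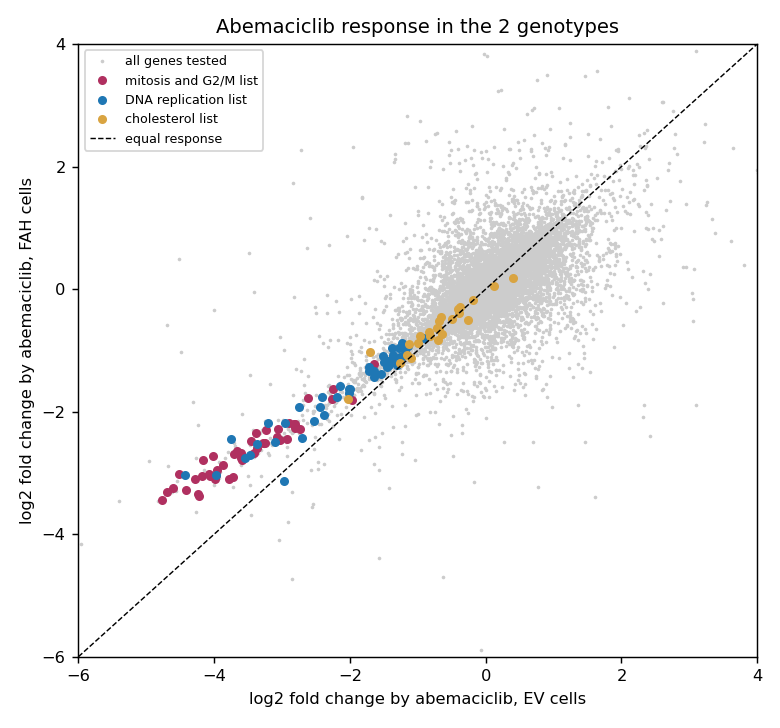
Log2 fold change of each tested gene by abemaciclib in EV cells (horizontal) against FAH cells (vertical), n = 3 libraries per group, with the mitosis, DNA replication and cholesterol lists coloured and a dashed line of equal response, and no error bars. PBK stood at -4.17 in EV cells and -2.80 in FAH cells.

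Under vehicle edgeR called few genes between the 2 genotypes, with FAH by far the largest difference among them. The count depended on the setting, with 323 genes called by DESeq2. GPNMB was lower in FAH cells at 16.4 ± 0.91 against 31.2 ± 2.21 CPM (log2 fold change -0.93 ± 0.08, n = 3 per group, edgeR adjusted p = 6.39e-05). TGFB2, which encodes a growth-restraining cytokine, was lower at 48.8 ± 1.71 against 80.5 ± 5.24 CPM (-0.72 ± 0.06, edgeR adjusted p = 2.17e-05). CAV1, a coat protein gene of membrane pits (-0.47 ± 0.06, edgeR adjusted p = 0.00255), and the collagen gene COL5A1 (-0.47 ± 0.06, edgeR adjusted p = 0.00379) were lower. TFF1 (349.2 ± 9.68 against 252.4 ± 15.1 CPM, 0.47 ± 0.06, edgeR adjusted p = 0.00255) and the helix-loop-helix gene ID1 (0.61 ± 0.09, edgeR adjusted p = 0.0039) were higher. These 7 genes, FAH included, kept their calls whichever library was left out. In a fit of only the vehicle groups CAV1 (0.0643), COL5A1 (0.107) and ID1 (0.114) were not called, and TFF1 was lost with length offsets (0.144).

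The other called genes that the rule named under vehicle lost their calls in 1 or more fits with 1 library left out. Higher in FAH cells were SPDEF (0.37 ± 0.06, edgeR adjusted p = 0.00945), lost without FAH vehicle 2 (0.0811) alone of the libraries, and FADS2 (0.48), SLIT1 (0.74), XBP1 (0.24), GPER1 (0.48), IRX3 (0.50), DNAJA3 (0.48) and B3GALT5 (0.54), each lost in between 3 and 5 of 6 fits with 1 library left out. Lower were COL5A2 (-0.64), AMER2 (-0.41) and the members of copied families HERC2P3 (-0.81) and NPIPB12 (-0.52), lost in between 3 and 6 of those fits. The highest adjusted p of all these was 0.254, for B3GALT5 and IRX3 without FAH vehicle 3. In a fit of only the vehicle groups none of them was called but COL5A2 (0.0301), and SPDEF stood at 0.218 there and at 0.0801 with unmatched transcripts kept. At least 2-fold differences were those of FAH, PCSK2 (1.89), NELL2 (1.54) and AMT (-1.75), the last 3 chosen after the values were seen and low in reads. Proliferation genes did not differ measurably, with MKI67 at 0.04 (edgeR adjusted p = 0.964), CCNB1 at 0.04 (0.837), CCNE2 at 0.00 (0.997), MCM2 at 0.12 (0.457) and CCND1 at -0.01 (0.917). Nor did CDKN1A (0.16, 0.299), ESR1 (0.13, 0.271), MYC (-0.02, 0.942), NEAT1 (-0.57, 0.269) or MALAT1 (-0.70, 0.217), though a p above the threshold does not show that levels were equal, and DESeq2 called MALAT1 lower (0.0457). In all 38 genes were called, 20 higher and 18 lower (between 16 without FAH vehicle 2 and 70 without EV vehicle 2), against 2149 at an unadjusted p below 0.05.

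Small shifts of whole lists were called under vehicle, all upward in FAH cells. Tyrosine and phenylalanine genes were higher (median 0.16, camera adjusted p = 8.79e-19), where edgeR called FAH of 15 genes (2 over the list alone) and DESeq2 also MIF (0.0498). Without FAH the list stood at 0.14 (camera adjusted p = 0.0207, adjusted p = 0.214 with an estimated correlation). Of the oestrogen receptor targets TFF1 and XBP1 rose (8 and 2 lower over the list alone, median 0.07, camera adjusted p = 0.000338, adjusted p = 0.189 with an estimated correlation). Of the luminal genes SPDEF rose (median 0.09, camera adjusted p = 0.00283, adjusted p = 0.235 with an estimated correlation). Fatty acid synthesis genes (median 0.08, FADS2 rose with edgeR, 3 over the list alone) were called with camera adjusted p = 0.00283, and adjusted p = 0.179 with an estimated correlation. FADS1 was called as well with DESeq2 (0.0114) and with the GC trend removed (0.0355). TCA cycle genes (median 0.07, camera adjusted p = 0.0127, adjusted p = 0.179 with an estimated correlation) and respiratory chain genes (median 0.07, camera adjusted p = 0.00109, adjusted p = 0.361 with an estimated correlation) had 0 genes called by edgeR, and DESeq2 called ATP5F1B of the latter (0.0484). Glycolysis and hypoxia genes (median 0.13, camera adjusted p = 0.00109, adjusted p = 0.524 with an estimated correlation) had 0 called by edgeR, with 6 higher and 1 lower over the list alone. DESeq2 called PKM (0.000505), GAPDH (0.0141) and PGAM1 (0.0415) higher and VEGFA (0.0493) lower, and PKM was also called with limma-voom (0.0458) and without EV vehicle 2 (0.047). With length offsets the fatty acid (0.108), TCA (0.17), respiratory (0.0949) and glycolysis (0.0578) calls were lost, and leaving out FAH vehicle 2 ended the TCA call (0.0743).

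EV vehicle library 2 stood apart from its mates, and without it the glycolysis median fell to 0.02 (camera adjusted p = 0.171) and that of the respiratory chain genes to 0.04 with its call kept. Without EV vehicle 3 the respiratory chain median was 0.12 and that of fatty acid genes 0.04, while luminal genes stood at 0.04 without FAH vehicle 3, oestrogen receptor targets at 0.12 without FAH vehicle 1 and tyrosine genes at 0.24 without EV vehicle 1, all still called. Of the lists called under vehicle the tyrosine list held with an estimated correlation, but not once FAH itself was left out. Mitosis (0.03, camera adjusted p = 0.568) and DNA replication genes (0.05, camera adjusted p = 0.106) were not called, nor were interferon-stimulated genes (median -0.05, mean -0.36, camera adjusted p = 0.164). Mitochondrially encoded mRNAs (median 0.00, camera upward, adjusted p = 0.903) turned to -0.17 without EV vehicle library 3 (camera adjusted p = 5.11e-06), whose mitochondrial share was 2.84% against 4.14 and 4.35% in its mates. The estimated correlation between these mRNAs was 0.854, far above the preset 0.01, so that p overstates the evidence. With all libraries the camera adjusted p was 0.97 with an estimated correlation. Antigen presentation genes had a median of 0.06 and a mean of -0.06, and stromal markers a median of 0.01 with the test downward, neither called. None of the 13 other lists was called, XBP1 being the only called member of the ER chaperone list.

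**Figure D4:**
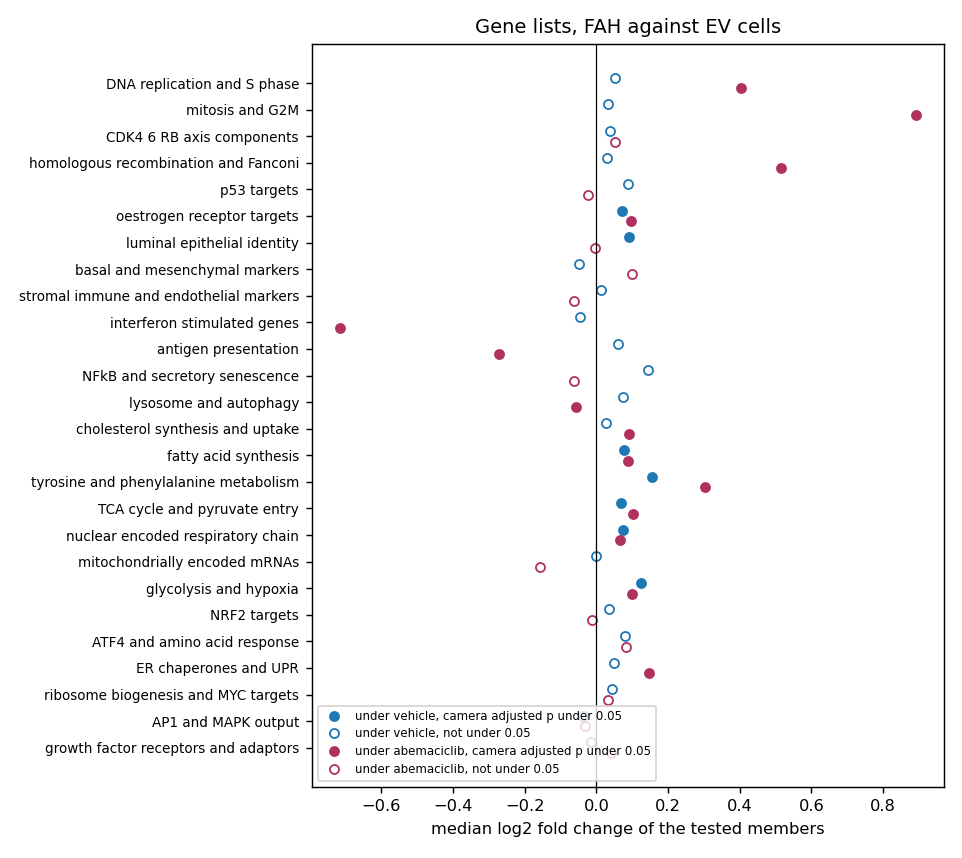
Median log2 difference between FAH and EV cells over the tested members of each list (horizontal axis) under vehicle and under abemaciclib, n = 3 libraries per group, without error bars. The interferon-stimulated list stood at -0.05 under vehicle and -0.71 under abemaciclib.

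Under abemaciclib FAH cells held more mRNA of cell cycle genes than EV cells did. CCNB1 stood at 59.1 ± 4.86 against 41.4 ± 1.44 CPM (log2 fold change 0.51 ± 0.06, n = 3 per group, edgeR adjusted p = 0.000514). UBE2C, which encodes an enzyme of mitotic exit, stood at 15.1 ± 2.92 against 6.83 ± 0.643 CPM (1.14 ± 0.11, edgeR adjusted p = 0.00011). CCNE2 stood at 6.61 ± 2.01 against 2.67 ± 0.64 CPM (1.29 ± 0.21, edgeR adjusted p = 0.00613). TFF1 was higher at 116.9 ± 6.61 against 50.4 ± 3.62 CPM (1.21 ± 0.06, edgeR adjusted p = 5.08e-08). GPNMB was lower at 94.2 ± 10.1 against 214.2 ± 9.44 CPM (-1.19 ± 0.07, edgeR adjusted p = 4.58e-07). PCSK2, a hormone-processing protease gene (1.93 ± 0.20, edgeR adjusted p = 0.000112), and NELL2 (1.54 ± 0.20, edgeR adjusted p = 0.000773) were higher. VEGFA was lower (-0.65 ± 0.08, edgeR adjusted p = 0.000314, lost with length offsets at 0.0764), as were PSG5 (-1.26) and the readthrough gene STX16-NPEPL1 (-1.66 ± 0.20), both uncertain as near copies. All of these calls held whichever library was left out. KIF14, a mitotic motor gene (1.38), was higher and ATG9B (-1.24), LAT (-1.12) and the copied GOLGA6L5P (-1.11) lower. KIF14 was lost in 3 fits, at most at 0.0674 without EV abemaciclib 3, and ATG9B in 1, at 0.0561 without EV abemaciclib 1. LAT and GOLGA6L5P were lost in 5 fits each, at most at 0.113 without FAH abemaciclib 3 and 0.132 without FAH abemaciclib 1. Of 763 genes called 384 were higher and 379 lower, 46 and 32 at least 2-fold. Without 1 of the compared libraries between 242 (EV abemaciclib 1) and 492 (FAH abemaciclib 2) were called, and without EV vehicle library 2, which enters the fit but not the contrast, 1752.

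Mitosis genes were higher in 35 of 45 cases and lower in 0 (45 over the list alone, median 0.89, camera adjusted p = 3.69e-77), including PBK (1.26 ± 0.11), AURKB (1.31 ± 0.21), AURKA (0.72), MAD2L1 (0.77) and DLGAP5 (1.53 ± 0.25). DNA replication genes were higher in 25 of 44 (34 over the list alone, median 0.40, camera adjusted p = 1.23e-39), with MCM2 (0.35), MCM3 (0.41), MCM6 (0.48 ± 0.05) and CDC6 (0.96). Of the homologous recombination genes 10 of 21 were higher (14 over the list alone, median 0.51, camera adjusted p = 1.19e-13, adjusted p = 0.055 with an estimated correlation), EXO1 (1.47 ± 0.19), BRCA1 (0.63) and BRCA2 (0.56) among them. With length offsets BRCA1 (0.0713) and BRCA2 (0.136) were not called. The CDK4/6-RB axis had 4 higher genes, RBL1 (0.58), CDC25A (0.67), CDKN2C (0.85) and TFDP1 (0.20), and 0 lower (5 over the list alone, median 0.05, camera adjusted p = 0.0782). Each of the 4 was lost in between 2 and 5 of 6 fits with 1 library left out, at most at 0.0929 without EV abemaciclib 1. MKI67 (1.42 ± 0.27, edgeR adjusted p = 0.0238) was lost without any 1 EV abemaciclib library, at most at 0.0842 without library 3, and E2F1 (0.63, edgeR adjusted p = 0.0267) in 5 fits, at most at 0.0818 without EV abemaciclib 2. CCNA2 (0.96, edgeR adjusted p = 0.05), RB1 (0.26, 0.0619), CCND1 (-0.10, 0.163), CDK6 (-0.16, 0.185), CDKN1A (-0.02, 0.898), ESR1 (0.07, 0.499) and MYC (0.02, 0.937) were not called. Other fits did call CCNA2 (6 settings, 0.00227 to 0.0462, and without FAH abemaciclib 1 at 0.017 or 2 at 0.00784), RB1 (6 settings, 0.00974 to 0.0484) and CDK6 (0.0291 with the GC trend removed, 0.0197 from only the groups compared). FAH abemaciclib library 2 had the highest mitosis score of its group, 4.19 against 3.64 and 3.67.

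Interferon-stimulated genes were lower in FAH cells given abemaciclib, 9 of 29 called lower and 0 higher (16 over the list alone, 27 with a negative sign, median -0.71, camera adjusted p = 1.15e-15, adjusted p = 0.0761 with an estimated correlation). DTX3L (-0.41, edgeR adjusted p = 0.00703), SAMD9 (-0.93, 0.012), HERC6 (-0.72, 0.0224) and IFIH1 (-0.68, 0.0232), genes of antiviral defence, had the smallest p. Each of these was lost in between 1 and 4 of 6 fits with 1 library left out, without EV abemaciclib 3 in the case of DTX3L (0.0554), HERC6 (0.106) and IFIH1 (0.101), and at most at 0.063 without FAH abemaciclib 3 for SAMD9. IFIT1 (14.1 ± 4.54 against 35.4 ± 9.18 CPM, -1.33 ± 0.31, edgeR adjusted p = 0.0426) and CMPK2 (-1.14, 0.0369) were each lost in 5 of those fits, at most at 0.13 without FAH abemaciclib 2 and 0.168 without EV abemaciclib 3. Of the antigen presentation genes TAPBP (-0.29) and NLRC5 (-1.14) were lower (2 higher and 5 lower over the list alone, median -0.27, camera adjusted p = 0.0119, adjusted p = 0.0761 with an estimated correlation). Both genes were lost in 5 fits, at most at 0.24 without EV abemaciclib 1 and 0.093 without FAH abemaciclib 3. The nuclear RNA NEAT1 was lower too (-1.04, edgeR adjusted p = 0.0207, lost in 4 fits, at most at 0.0837 without EV abemaciclib 1). Reads on transcripts with retained introns made up 3.19, 3.79 and 3.39% in these FAH libraries and 5.04, 4.21 and 4.44% in these EV libraries.

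Metabolic lists were slightly higher in FAH cells under abemaciclib. Of 15 tyrosine genes 5 were higher, FAH, GOT1 (0.37), GCH1 (0.34), GOT2 (0.19) and MAOA (0.67), the last outside the naming rule and chosen after the values were seen (6 over the list alone, median 0.30, camera adjusted p = 1.37e-19). The list stood at 0.25 without FAH (camera adjusted p = 0.000334, adjusted p = 0.0513 with an estimated correlation). GCH1 was lost without 2 of the libraries, at most at 0.0605 without EV abemaciclib 3, and GOT2 without 4, at most at 0.106 without the same library. FADS1 (0.43), FADS2 (0.57) and SCD (0.24) were the higher fatty acid genes (5 over the list alone, median 0.09, camera adjusted p = 0.000293). That median was 0.15 without EV abemaciclib 2 or FAH abemaciclib 3. SQLE (0.28), IDI1 (0.24) and ACAT2 (0.36) were the higher cholesterol genes (5 over the list alone, median 0.09, camera adjusted p = 0.00126, adjusted p = 0.0639 with an estimated correlation). IDI1 was lost at most at 0.0563 without EV abemaciclib 3 and ACAT2 at 0.102 without EV abemaciclib 1. Length offsets ended the calls of FADS1 (0.111), FADS2 (0.0507), IDI1 (0.131) and ACAT2 (0.0613). TCA cycle genes were higher (median 0.10, 10 over the list alone, camera adjusted p = 2.9e-05) with PDHB (0.29), IDH2 (0.22) and SDHA (0.22), lost at most at 0.0867, 0.0615 and 0.133 without EV abemaciclib 1, 3 and 1.

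Oestrogen receptor targets were higher (TFF1, TFF3 at 0.79 and RERG at 0.50, 6 and 1 lower over the list alone, median 0.10, camera adjusted p = 8.77e-05, adjusted p = 0.0761 with an estimated correlation). So were ER chaperone genes (HSP90B1 at 0.20 and PDIA6 at 0.17, 5 over the list alone, median 0.15, camera adjusted p = 0.00181, adjusted p = 0.0761 with an estimated correlation). RERG was lost in 4 fits, at most at 0.151, HSP90B1 in 1, at 0.0713, and PDIA6 in 5, at most at 0.0812, each without EV abemaciclib 1. Lysosome genes were lower with TPP1 (-0.32) and CTSA (-0.21) called (1 higher and 4 lower over the list alone, median -0.06, camera adjusted p = 0.0357, adjusted p = 0.494 with an estimated correlation), a list call lost without EV abemaciclib 2 (0.225), EV abemaciclib 3 (0.0647) or FAH abemaciclib 2 (0.412). TPP1 and CTSA were lost in all 6 fits, at most at 0.141 without EV abemaciclib 1 and 0.225 without EV abemaciclib 3. The glycolysis list (PGK1 0.17, PGAM1 0.23 and ALDOC 0.57 higher, VEGFA lower, 5 and 2 over the list alone, median 0.10, camera adjusted p = 0.0432, adjusted p = 0.684 with an estimated correlation) was lost without EV abemaciclib 2 (0.0574) or FAH abemaciclib 1 (0.051). The respiratory chain list, with only ATP5F1B (0.17) higher (median 0.07, camera adjusted p = 0.0436, adjusted p = 0.508 with an estimated correlation), was lost without EV abemaciclib 2 (0.0574) or FAH abemaciclib 1 (0.14). PGK1 was lost in 4 fits and ATP5F1B in 4, at most at 0.0959 and 0.101, and ALDOC in 1 at 0.0555, each without EV abemaciclib 1.

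In lists that were not called, AGR2 (0.36), ODC1 (0.31), SLC7A5 (0.38), FGFR4 (0.37) and PLK2 (0.23) were higher in FAH cells whichever library was left out, PLK2 being lost with length offsets (0.575). SPDEF (0.24) was higher, lost in 4 fits, at most at 0.0873, and ELF3 (-0.36) and DDIT3 (-0.62) lower, lost in 2 and 3 fits, at most at 0.0717 and 0.102, each without EV abemaciclib 1. Medians and test directions differed for p53 targets (-0.02, test upward), luminal identity (0.00, upward) and NF-kB genes (-0.06, mean 0.07, upward). Stromal markers (median -0.06, mean 0.16) and AP1 genes (-0.03, mean 0.04) had a downward test like their medians but a mean of the other sign. Mitochondrially encoded mRNAs were lower without a call (median -0.16, camera adjusted p = 0.0515). With an estimated correlation the mitosis, replication, fatty acid and TCA calls held, and the tyrosine call with FAH in the list but not without it (adjusted p = 0.0513).

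The 2 responses to abemaciclib differed most in cell cycle genes, which were lowered less in FAH cells. PBK, a mitotic kinase gene, fell by 4.17 in EV and by 2.80 in FAH cells, a difference of 1.37 ± 0.14 (n = 3 per group, edgeR adjusted p = 0.000774), and TFF1 by 2.32 and 1.58, a difference of 0.75 ± 0.09 (edgeR adjusted p = 0.00307). Both calls held whichever library was left out, with PBK lost under limma-voom (0.0682). All 45 mitosis genes had a positive difference (6 called, 43 over the list alone, median 0.86, camera adjusted p = 4.45e-81, adjusted p = 0.0642 with an estimated correlation). Replication genes (MCM6 alone called, 24 over the list alone, median 0.37, camera adjusted p = 3.2e-33, adjusted p = 0.0761 with an estimated correlation) and homologous recombination genes (EXO1 alone called, 12 over the list alone, median 0.43, camera adjusted p = 5.21e-14, adjusted p = 0.0761 with an estimated correlation) went the same way. No list call of this comparison held with an estimated correlation.

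Single cell cycle genes were less stable here. PIMREG (1.94 ± 0.26, edgeR adjusted p = 0.014) was lost in 4 of 12 fits with 1 library left out, at most at 0.0632 without EV abemaciclib 1. UBE2C (1.03, edgeR adjusted p = 0.0179), MCM6 (0.44, 0.0347), CCNB1 (0.47 ± 0.09, 0.0443), EXO1 (1.52, 0.0347), CDKN3 (1.19, 0.0357), CEP55 (1.15, 0.0347), NDC80 (1.14, 0.0347) and CCNB2 (0.79, 0.0359) were lost in between 6 and 9 of those fits. For UBE2C the highest adjusted p was 0.0844, for CCNB1 0.171, for CCNB2 0.127 and for the others 0.124, each without FAH vehicle 1. With the replicate block within EV cells CCNB1 (0.0522), EXO1 (0.0512) and CEP55 (0.0718) were not called. MKI67 (1.39 ± 0.35, edgeR adjusted p = 0.296), CCNE2 (1.29, 0.133), CCNA2 (0.90, 0.453), CCND1 (-0.09, 0.72) and FAH (0.10, 0.838) were not called in the first place. MKI67 was called with DESeq2 (0.0179), and CCNE2 with DESeq2 (0.000163), length offsets (0.024) and without FAH abemaciclib 3 (0.00766). The called genes numbered 26, 22 upward and 4 downward (between 2 without FAH vehicle 1 and 63 without FAH abemaciclib 1), against 1358 at an unadjusted p below 0.05.

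Outside the cell cycle, interferon-stimulated genes had a negative difference (median -0.67, mean -0.37, camera adjusted p = 4.04e-11, adjusted p = 0.224 with an estimated correlation), with 0 genes called by edgeR, 0 over the list alone and SAMD9 called by DESeq2 (0.0487). Their score in EV cells was 3.71 ± 0.039 under vehicle and 4.08 ± 0.246 under abemaciclib, and in FAH cells 3.61 ± 0.175 and 3.43 ± 0.301. Antigen presentation (median -0.23, mean -0.53, camera adjusted p = 0.00255, adjusted p = 0.0761 with an estimated correlation) and lysosome genes (median -0.14, camera adjusted p = 6.76e-05, adjusted p = 0.224 with an estimated correlation) were likewise negative without an edgeR call, though DESeq2 called CTSA (0.0182), the lysosome median moving to -0.08 without EV vehicle 2, -0.09 without EV abemaciclib 2 and -0.06 without FAH abemaciclib 2. Luminal identity genes (median -0.12, camera adjusted p = 0.0413, adjusted p = 0.347 with an estimated correlation) lost their call in 9 of 12 fits with 1 library left out, at most at 0.275 without EV abemaciclib 2. Cholesterol genes (median 0.07, camera adjusted p = 0.0405, adjusted p = 0.224 with an estimated correlation) lost theirs without EV vehicle 1 (0.128), EV vehicle 3 (0.171), FAH vehicle 1 (0.0623) or FAH vehicle 2 (0.0654). DHRS2, a dehydrogenase gene, fell only in EV cells (difference 1.12, edgeR adjusted p = 0.0251, lost in 8 fits, at most at 0.104 without FAH vehicle 3). TRIM14 (-0.75, 0.0435), C14orf132 (-0.44, 0.0357), CLN3 (-0.43, 0.0387) and BCL3 (-0.42, 0.0347) had negative differences, lost in between 9 and 11 fits. TRIM14 was lost at most at 0.146 without FAH vehicle 3, C14orf132 and CLN3 at 0.143 and 0.149 without FAH vehicle 2, and BCL3 at 0.124 without FAH vehicle 1. Medians and other measures differed in sign for oestrogen receptor targets (-0.01, mean 0.05, test upward), NF-kB genes (-0.16, mean 0.04) and glycolysis genes (-0.02, mean 0.01), none of them called.

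**Figure D5:**
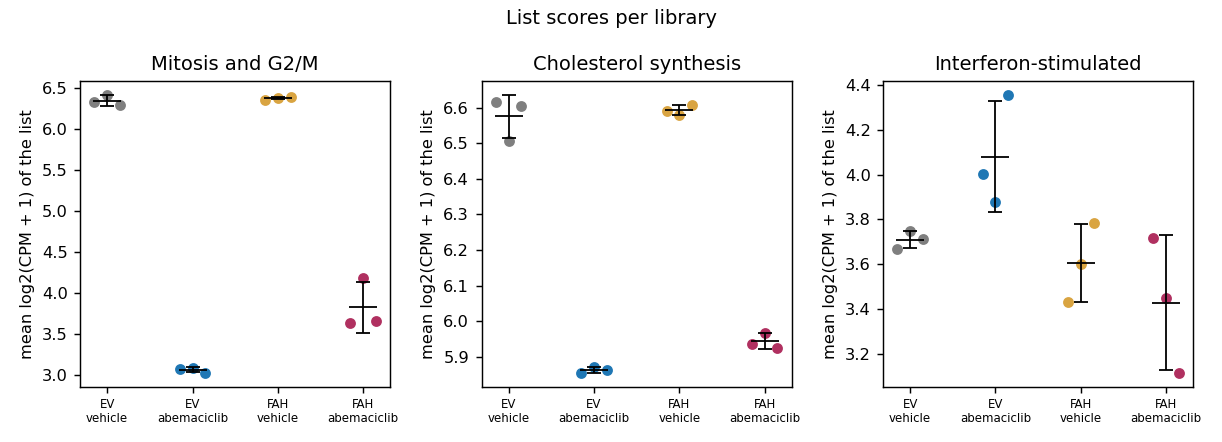
Mean log2(CPM + 1) over the members of gene lists in each library of the 4 groups, with bars at mean and SD (n = 3). The mitosis score was 6.34 and 3.07 in EV cells and 6.38 and 3.83 in FAH cells, under vehicle and abemaciclib.

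The mitosis score dropped from 6.34 ± 0.064 to 3.07 ± 0.03 in EV cells and from 6.38 ± 0.017 to 3.83 ± 0.309 in FAH cells (exact permutation p = 0.1 each, the smallest possible). DNA replication scores moved from 6.15 to 4.16 and from 6.20 to 4.60. In both genotype comparisons 11 genes were higher and 11 lower together, against 0.5 and 0.4 expected, with 0 in opposite directions, and the 2 sets of differences share no libraries (Pearson 0.133, Spearman 0.289). EV vehicle library 2 lay apart from its mates, with a median absolute deviation of 0.254 log2 CPM against 0.079 to 0.146 in the other libraries.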

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

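The tests of single libraries, of sequencing depth, of reads on retained introns and of a common factor, and the count of other groupings of the libraries, were chosen only after the result was seen. The tests of GC content, of transcript length and of mixed RNA were set down before they were run, but how the GC bound was read was settled after its value was seen.

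The first pattern is the weaker fall of cell cycle genes in FAH cells, with differences of 0.855 for the mitosis list, 0.366 for DNA replication and 0.425 for homologous recombination genes, calls lost with an estimated correlation (adjusted p = 0.0642, 0.0761 and 0.0761). It stood out as a difference in size between groups, where all 3 lists fell steeply in both genotypes, and no biological cause was tested. FAH abemaciclib library 2 alone may raise the mitosis value but cannot be all of it, since 0.653 remained without that library (camera adjusted p = 2.71e-89). RNA of vehicle-like cells mixed into the FAH abemaciclib libraries could give it. The share needed was 8.19% from the cholesterol genes against 8.13 ± 4.15% from the mitosis genes. Incompletely arrested cells and carry-over cannot be told apart on this measure. TCA cycle genes would need 33.2 ± 1.08%, but the measure takes the genotypes as equal apart from mixing. These genes were already slightly higher in FAH cells under vehicle (median 0.07, camera adjusted p = 0.0127, 0.179 with an estimated correlation), so their share cannot decide. Lysosome genes would need 28.77 ± 11.46%, fatty acid genes 14.22 ± 8.45%, replication genes 11.14 ± 5.46% and homologous recombination genes 9.83 ± 6.1%. One factor of 0.777 ± 0.055 on every response is neither shown nor excluded. Of 324 genes raised at least 2-fold on average of both genotypes 9.9% responded by more than it allows, above the bound of 5%. Their median ratio of FAH to EV responses was 0.84, below the upper end of 0.887 that the factor allows. The cholesterol change alone would leave the factor open (-0.65 where -0.554 was due, 1.91 standard errors, bound 2). A first choice of 384 genes on EV cells only, which favours the factor, gave 3.4%. That choice was replaced after its value was seen, so the count from the second choice cannot decide.

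The second pattern is the lower level of interferon-stimulated genes in FAH cells under abemaciclib (median -0.714), with a difference of -0.674 between the responses, and stood out because no gene of that list was called in the response difference. No test of a biological cause was run. EV abemaciclib library 3 alone may contribute but is not the whole cause (median -0.549 without it, camera adjusted p = 9.76e-11), nor is FAH abemaciclib library 3 (-0.548, camera adjusted p = 1.48e-11). Reads on retained introns, more frequent in EV cells, are not the whole cause (-0.708 without such transcripts, camera adjusted p = 3.46e-18). The genes move together, so the call could still rest on shared spread, as the adjusted p was 0.0761 with an estimated correlation.

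The third pattern is the distance of EV vehicle library 2 from its mates, 0.254 log2 CPM, where at most 0.146 was seen elsewhere. GC content may explain part of it, since removing its trend left 0.143, above the 0.107 that the other libraries reached at most after the same correction. The uncorrected 0.146 lies above that value, but it is the distance of EV vehicle 3 from a mean that holds library 2 itself. Uncorrected libraries of the other groups lay at most at 0.092 (FAH abemaciclib 2). The 0.143 left thus argues against GC content as the whole cause. Transcript length left 0.226 against at most 0.139 in the others and is excluded as the whole cause. Low depth is not the cause, as 0.092 was the highest distance among the 3 libraries with fewer reads.

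Other groupings of the same libraries into 3 against 3 were fitted in edgeR. For abemaciclib in EV cells, in FAH cells, and for genotype under vehicle and under abemaciclib, 10 groupings are too few for a share below 0.05, with 1, 1, 1 and 1 of them reaching the real counts of 5903, 4964, 38 and 763 and at most 1, 1, 2 and 1 genes in any other. For the response difference 4 of 100 groupings, the real one included, called at least 26 genes, a share below 0.05 that does not by itself exclude a random grouping. The highest other count was 169. The groupings with the most genes kept the abemaciclib libraries together by genotype while mixing vehicle libraries. They thereby retained the genotype difference under abemaciclib, for which the real groups gave 763 genes. Such groupings are not free of real differences, so neither the share nor the 169 can decide whether the 26 calls came from a random grouping.

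The remaining differences between the responses stood out as differences between groups. Antigen presentation genes gave -0.227, lysosome genes -0.138, luminal identity genes -0.119 and cholesterol genes 0.066. PIMREG (1.941), EXO1 (1.516), PBK (1.372), CDKN3 (1.194), CEP55 (1.152), NDC80 (1.139), UBE2C (1.025), CCNB2 (0.79), CCNB1 (0.473) and MCM6 (0.439) are cell cycle genes whose fall was smaller in FAH cells. TFF1 (0.745) and DHRS2 (1.123) fell less or not at all in FAH cells. TRIM14 (-0.753), C14orf132 (-0.443), CLN3 (-0.428) and BCL3 (-0.419) rose less or not at all in FAH cells. Of 9182 tested transcripts outside the annotation, edgeR called 431, 333, 2, 45 and 5 in the 5 comparisons, unusual in that whole genes may be missing from the gene totals, where keeping them changed the genotype count under abemaciclib to 490.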

How the results depend on the processing

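Calls of the abemaciclib responses were stable, and those of the genotype and response differences were not, with directions almost always kept. Of the list results with 1 library left out 868 kept their state, 38 gained a call, 29 lost it and 1 turned. That one was the mitochondrially encoded mRNAs under vehicle, from -0.173 without EV vehicle 3 to 0.126 without EV vehicle 2. The cause was not tested, though library 3 had the lowest mitochondrial share. Genes kept their calls in every such fit for 119 of 125 named genes in EV cells, 109 of 115 in FAH cells, 7 of 19 and 37 of 75 between genotypes under vehicle and abemaciclib, and 2 of 16 in the response difference. For all the changes of counts below the cause was not tested.

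Against a fold of 1.5, 927 and 648 genes were called in EV and FAH cells (31.7% and 26.2% higher, against 49.3% and 47.0%), and 2, 9 and 1 in the other comparisons. Leaving out 1 library of the groups compared gave 4980 to 6194 genes in EV cells and 3941 to 4290 in FAH cells. EV vehicle 2 was also left out of the fit for contrasts it is not part of, which gave 6104 genes in FAH cells and 1752 between genotypes under abemaciclib (964 higher, 788 lower).

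For genotype under vehicle, where 38 genes were called (52.6% higher), the count was 156 without a filter (39.1% higher), 25 with length offsets (36.0% higher), 112 with the GC trend removed, 20 with unmatched transcripts kept, 323 with DESeq2 and 7 from only the groups compared. Leaving out EV vehicle 1, 2 or 3 gave 35, 70 or 22 genes, and FAH vehicle 1, 2 or 3 gave 40, 16 or 19. Under abemaciclib, where 763 were called (50.3% higher), it was 506 with length offsets (63.2% higher), 1475 with the GC trend removed (66.5% higher), 490 with unmatched transcripts kept (77.6% higher), 721 with limma-voom (39.8% higher), 1380 with DESeq2 and 1666 from only the groups compared. Without EV abemaciclib 1, 2 or 3 it was 242, 453 or 316, and without FAH abemaciclib 1, 2 or 3 it was 383, 492 or 412. So the share of higher genes depends on the setting.

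For the response difference, with 26 genes, the count was 89 without a filter, 13 with length offsets, 51 with the GC trend removed, 13 with unmatched transcripts kept, 163 with DESeq2 and 2 with limma-voom. It was 6, 44 or 7 without EV vehicle 1, 2 or 3 and 3, 8 or 5 without EV abemaciclib 1, 2 or 3. It was 2, 5 or 3 without FAH vehicle 1, 2 or 3 and 63, 46 or 45 without FAH abemaciclib 1, 2 or 3.

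An additive replicate block over all groups left 18 genes under vehicle and 13 in the response difference. A call lost under the replicate block need not be a weaker effect, as the block also spends degrees of freedom. The replicate block within EV cells gave 6068 genes in EV cells and 30 in the response difference. It ended no list call, and the 5 calls of named genes that it ended are given with those genes. Of all genes it kept 5759 of the 5903 calls in EV cells and 22 of the 26 in the response difference.

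The Spearman correlation of the abemaciclib responses, 0.673, was 0.266 without a filter, 0.779 with the stricter filter, 0.616 with length offsets, 0.684 with the GC trend removed, 0.456 with unmatched transcripts kept, 0.653 with limma-voom and 0.733 from only the groups compared, and 0.617 to 0.647 with 1 library left out. That of the genotype differences, 0.289, was 0.111, 0.337, 0.256, 0.335 and 0.21 for the first 5 of these in the same order, 0.265 without retained-intron transcripts, 0.315 from only the groups compared and 0.219 to 0.288 with 1 library left out.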

Other observations

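Single growth factor receptor and adaptor genes changed with abemaciclib, and the response of the list did not differ measurably between genotypes (median 0.03, camera adjusted p = 0.674). In EV cells 10 of 22 rose and FGFR3 (-0.63), FGFR4 (-0.88) and MET (-0.31) fell (median 0.13, camera adjusted p = 0.107), with the PI3K regulators PIK3R3 (0.63) and PIK3IP1 (1.13) higher. In FAH cells 8 rose and FGFR3 (-0.39) and FGFR4 (-0.80) fell (11 and 2 over the list alone, median 0.18, camera adjusted p = 0.0316, adjusted p = 0.139 with an estimated correlation), PIK3IP1 (1.06), GRB10 (0.61) and PIK3R3 (0.61) rising. With length offsets that call was lost (0.0599). Of 24 genes of AP1 and MAPK output 8 rose in EV cells and EGR3 (-1.14) and DUSP5 (-0.54) fell (median 0.14, camera adjusted p = 0.153), among the risers PHLDA1 (1.04), JUNB (0.79) and EGR1 (0.53), which early growth signals induce. In FAH cells 6 rose and EGR3 (-1.02) alone fell (median 0.20, camera adjusted p = 0.0398, adjusted p = 0.292 with an estimated correlation), with PHLDA1 (0.98), DUSP4 (0.67) and EGR1 (0.64) higher. The AP1 call in FAH cells was lost without FAH vehicle 1 (0.0573) or FAH abemaciclib 2 (0.065).

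NRF2 targets, which answer oxidative stress, moved in both directions. In EV cells TKT (0.19), NQO1 (0.32) and AKR1C3 (0.58) rose and GCLM (-0.36), PGD (-0.27), AKR1C2 (-0.44), TXN (-0.33) and EPHX1 (-0.17) fell, GCLM, TXN and EPHX1 chosen after the values were seen (median 0.03, mean -0.03, camera upward, adjusted p = 0.968). In FAH cells 2 rose and 7 fell (2 and 8 over the list alone, median -0.08, camera adjusted p = 0.667), with NQO1 at 0.30, AKR1C3 at 0.66 and AKR1C2 at -0.41. AKR1C2 and AKR1C3 are close copies, so their opposite signs are uncertain. Several genes that differed between the genotypes under vehicle also responded to abemaciclib and were chosen after the values were seen. TGFB2 rose in EV cells (0.82 ± 0.06, edgeR adjusted p = 2.01e-08) and in FAH cells (1.04 ± 0.06, edgeR adjusted p = 2.47e-09), COL5A1 rose in both (1.60 and 1.35), and ID1 did as well (0.71 and 0.47). CAV1 fell in EV cells (-0.57 ± 0.06, edgeR adjusted p = 2.02e-06) but did not change measurably in FAH cells (0.07 ± 0.06, edgeR adjusted p = 0.441), a difference of 0.64 (edgeR adjusted p = 0.00999). That call was lost without FAH vehicle 1, where only 2 genes, PBK and TFF1, stayed called.

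Transcripts with retained introns took 3.55, 3.21 and 2.85% of reads in FAH vehicle libraries and 3.90, 4.12 and 4.03% in EV vehicle libraries, so the genotypes differed in this measure in both treatments. Reads on unmatched transcripts averaged 7.126% and 6.999% in EV cells (abemaciclib and vehicle) and 6.988% and 6.855% in FAH cells. The first principal component held 33.2% of the variance and the second 10.5%, on which EV vehicle library 2 stood at 56.6 with the others between -28.9 and 11.9.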
